A study of Sus scrofa with 9 samples.

How the data were processed

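Nascent RNA was measured by GRO-seq, a nuclear run-on assay that reads RNA polymerases caught in the act of transcription, in myocardium of 3 female farm pigs. A coil closed the distal left anterior descending coronary artery, and tissue was taken 24 hours later. Per the labels, the heart tissue was minced and treated with collagenase, the cells were filtered and nuclei were extracted before the run-on. Each pig gave a healthy, a border zone and an ischemic sample, so that 9 libraries fall into 3 groups of 3.

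The authors aligned the reads to the pig genome build susScr3 with Bowtie, whose version is not given in the sources used here. The deposited table holds RPKM, reads scaled by the length of the annotated span and by the library total, for 4882 annotated transcript positions in 1 column per library. It also lists the span and the exon length of each position in base pairs, per the file headers. The counting program, the strand setting, the treatment of duplicate reads and the rule for reads with several positions are not given in the sources used here. Each RPKM value multiplied by the span and by the library total was a whole number of reads within 0.01 reads, for 100% of the nonzero values, which gave the library totals and the reads behind each value. The span includes introns, so intron reads count. Coordinates are those of the table, on susScr3, and a Sscrofa11.1 RefSeq table served for gene names and RNA classes only. In 8 of 9 libraries read counts from 1 to 30 were multiples of 3 more often than the 33.3% of an even spread, with 53.2% in ischemic replicate 3 and 32.8% in ischemic replicate 1. The reads of a library are therefore not known to be independent molecules, and the intervals and floors given cover counting error only.

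Library totals were 2730083, 3426095 and 6531658 reads in healthy, 3550940, 7005976 and 2187977 reads in border zone, and 2134087, 1140910 and 883656 reads in ischemic replicates 1 to 3. A floor of 3 reads over a group was used where a group held no read. The fold against such a group is given as a lower bound from pooled reads, and a group with 1 to 3 reads is given with an exact 95% counting interval. No fold is given where the other group lies under the floor too.

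Values were taken to log2(RPKM + 0.1), and the 2384 positions with a mean of at least 0.5 RPKM over the 9 libraries were tested. They belong to 2104 genes, and 1027 positions held no read in any library. Fitted fold changes come from means of these logs and can be smaller or larger than the ratio of mean RPKM, above all for weakly transcribed positions. The fit was limma 3.58.1 in R 4.3.3, with the 3 groups as terms, all 9 libraries in the fit, and eBayes with trend and robust settings. Values were compared for ischemic against healthy, border zone against healthy, and ischemic against border zone, 2-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Table preparation and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

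Several transcript positions can share a gene symbol. Each position was tested as listed, and for gene lists and named genes the position with the longest span stood for the gene, which gave 2014 genes. The position with the highest mean RPKM had been fixed for this purpose, and the longest span, which does not depend on the measured values, replaced it after the data were seen. The highest mean was kept as another setting. Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over all lists tested, for lists with at least 5 measured members. The filter takes the mean over all 9 libraries, so a gene near 0 in healthy myocardium was measured only where another group was high. Of the genes in the table, 5 of 13 neutrophil, 12 of 21 macrophage, 17 of 32 cytokine and 4 of 23 lymphocyte genes were measured. This selection can raise the share of measured members that rose. The same test with an estimated correlation and the self-contained test fry were run beside it. Counts of members past the threshold are given over all genes tested and adjusted over the list alone.

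The gene lists covered sarcomere and Z-disc, cardiac calcium handling and ion channels, cardiac transcription factors, the fetal gene programme and wall stress, fatty acid uptake and oxidation, and oxidative phosphorylation and the citrate cycle. They also covered glycolysis and hypoxia response, immediate early and stress-kinase genes, heat shock proteins, the unfolded protein response, inflammatory cytokines, the NF-kB pathway, interferon-stimulated genes, TGF-beta signalling, matrix proteases, p53 targets, NRF2 targets and ribosomal protein genes. Cell type lists covered macrophages, neutrophils, lymphocytes, endothelium, smooth muscle, fibroblasts and matrix, adipocytes, erythroid cells, the epicardium with Schwann cells, and the cell cycle. A pair of lists held muscle and injury microRNA loci. Named genes follow a rule with 3 parts per comparison. The parts are the 8 rising and 8 falling genes with the largest change among those past the threshold in 1 direction in all 3 pigs, up to 4 members per list with the smallest p, and a panel of cardiac, inflammatory and microRNA genes. Of the panel, MYH6 and ATF3 are not in the table, and PPARGC1A, CXCL8, HMOX1 and CD163 lay under the filter. The lists, the rule, the comparisons, the test and its threshold, and the other settings tried, except those named as chosen later, were fixed before the data were examined.

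The pig numbers in the labels mark the animal, so they pair the samples across groups. As a check, deviations from the group means correlated on average 0.0784 between libraries of the same pig, from -0.0367 to 0.179, across genes. The average of -0.0392 between libraries of different pigs is nearly fixed by this, since the deviations of a group sum to 0. The main comparisons carry no pig term, and a fit with pig as a block was run as the paired alternative.

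Other settings tried were pseudocounts of 0.02 and 0.5, no filter, a filter at a mean of 2 RPKM, quantile normalization, libraries scaled to the same median, eBayes without trend or robust settings, pig as a block, a fit on the 2 groups of a comparison alone, 1 value per gene by the mean of its positions, an estimated correlation, fry, and leaving out each library or each pig. Settings chosen after seeing the data were limma-voom on the recovered reads, reads thinned to the total of the shallowest library, positions under 300 bp left out, the 2 shallowest libraries left out, and 1 position per gene by the longest span or the highest mean. The 2 shallowest libraries are ischemic replicates 2 and 3, so that setting leaves 1 ischemic library and its calls are not given.

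The test was checked on simulated data with known changes, 2404 simulated genes tested and a biological SD of 0.5 log2 units. Of simulated 4-fold changes it found 71.4% in ischemic against healthy, 52.6% in border zone against healthy and 74.1% in ischemic against border zone. Of 2-fold changes it found 4%, 1.06% and 12.4%, and unchanged genes made up 3.7%, 0% and 7.57% of its calls. In this simulation changes of about 2-fold were thus mostly missed at this depth and number of pigs. The SD and the number of changed genes were set and not taken from the data, so the shares found in the data can differ.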

Results

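Nascent transcription was measured by GRO-seq in 9 libraries from the myocardium of 3 pigs, 24 hours after a coil closed the distal left anterior descending coronary artery. Healthy, border zone and ischemic myocardium of each pig make 3 groups of 3 libraries. Values are RPKM over the whole annotated span, introns included, on the susScr3 build. Depth differed between groups, with 2730083 to 6531658 reads per healthy library, 2187977 to 7005976 per border zone library and 883656 to 2134087 per ischemic library. The median position kept for testing held 45, 48 and 94 reads in healthy, 75, 134 and 40 reads in border zone and 46, 20 and 16 reads in ischemic replicates 1 to 3. Positions annotated as ribosomal RNA took 2.24%, 1.06% and 0.621% of the healthy libraries, 1.36%, 0.733% and 1.62% of the border zone libraries and 2%, 4.39% and 3.85% of the ischemic libraries. Across genes, which are not independent replicates, libraries of a group correlated with r of 0.73 to 0.75 in healthy, 0.71 to 0.74 in border zone and 0.62 to 0.69 in ischemic myocardium, against 0.42 to 0.57 between healthy and ischemic libraries. Border zone libraries correlated with r of 0.55 to 0.75 with healthy and 0.58 to 0.72 with ischemic libraries, which overlaps the ranges within groups, and border zone replicate 2 reached 0.69 to 0.75 with healthy libraries.

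The comparison of ischemic with healthy myocardium asks which genes were transcribed differently at the site of the infarct. Many genes of contraction, calcium handling and oxidative metabolism fell in ischemic myocardium, and many of inflammation, leukocytes, matrix turnover and the response to hypoxia rose. ATP2A2, the calcium pump of the sarcoplasmic reticulum (NM_213865, chromosome 14 from 33446619 to 33491489), fell 5.51-fold, from 22.9 ± 4.25 to 4.23 ± 1.72 RPKM (mean ± SD, n = 3 each, folds from the means of log2 RPKM with 0.1 added). CD36, a fatty acid transporter (NM_001044622, chromosome 9 from 110040077 to 110102645), fell 8.44-fold, from 6.89 ± 0.976 to 0.789 ± 0.422 RPKM. IL1B, which encodes interleukin 1 beta (NM_214055, chromosome 3 from 45319296 to 45326287), rose 55.7-fold, from 0.209 ± 0.0485 to 18.7 ± 10.5 RPKM. SPP1, which encodes the matrix protein osteopontin (NM_214023, chromosome 8 from 140307938 to 140315415), rose 34.3-fold, from 0.124 ± 0.0781 to 7.27 ± 0.445 RPKM. Of 2384 positions tested, 442 were higher and 217 lower at an adjusted p under 0.05 (limma), while 965 had an unadjusted p under 0.05, where chance would give 119. These 659 positions belong to 617 genes, 412 higher and 205 lower. All 442 higher positions were higher in 3 of 3 pigs, and 216 of the 217 lower ones were lower in 3 of 3 pigs. The positions were called on these same libraries, so such agreement is largely built in, here and in the other comparisons. The median log2 fold change of all positions was 0.21. With the libraries scaled to the same median, 337 positions were higher and 295 lower, and quantile normalization gave 249 higher and 251 lower, so the excess of higher positions depends on the scaling. The count was 362 without healthy replicate 2 and 412 without healthy replicate 3, and 346 with a filter at a mean of 2 RPKM, which leaves fewer positions to test.

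**Figure D1:**
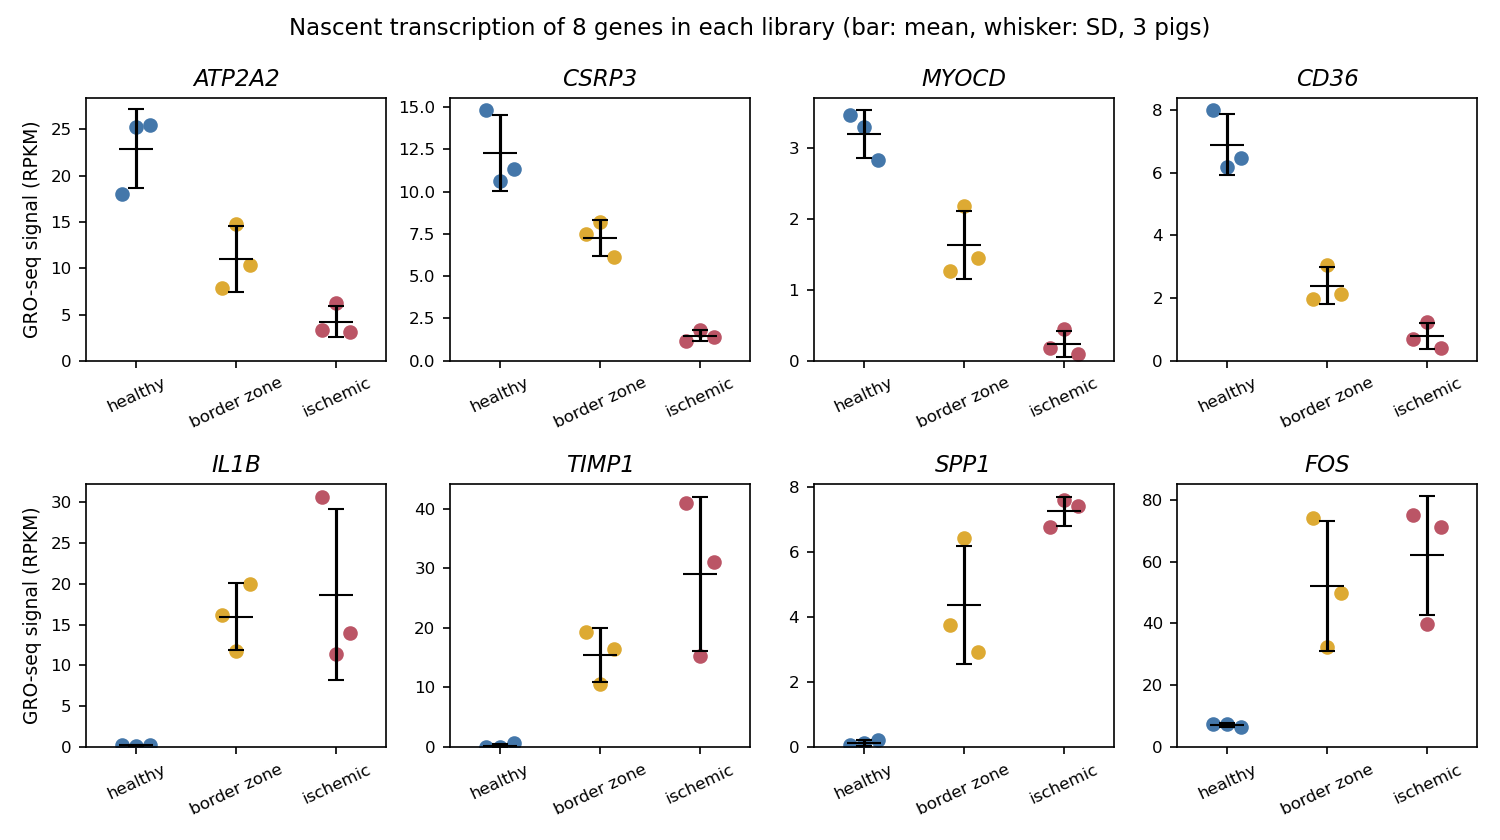
RPKM of ATP2A2, CSRP3, MYOCD, CD36, IL1B, TIMP1, SPP1 and FOS in healthy, border zone and ischemic myocardium, with 1 point per library, a bar at the mean and whiskers of 1 SD that stop at 0 (n = 3). ATP2A2 averages 22.9 RPKM in healthy, 11 in border zone and 4.23 in ischemic myocardium, while IL1B averages 0.209, 16 and 18.7 RPKM.

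Many genes of the heart muscle cell fell in ischemic myocardium. In the sarcomere and Z-disc list 9 of 14 measured genes fell and 0 rose, and adjusted over the list alone 11 fell. CSRP3, a muscle LIM protein of the Z-disc, had a log2 fold change of -2.97 ± 0.25 (± SE, adjusted p = 0.000337), and ACTN2, alpha-actinin, had -2.97 ± 0.36 (adjusted p = 0.00141). The list was lower by camera (adjusted p = 9.87e-07, and adjusted p = 0.205 with an estimated correlation). MYH7, the slow myosin heavy chain, stayed over the threshold at -1.43 ± 0.50 (adjusted p = 0.0647), and passed with pig as a block (adjusted p = 0.0303). TNNT2, cardiac troponin T, fell with a log2 fold change of -1.45 ± 0.43 (adjusted p = 0.0393), a call that was lost without any of 8 libraries, with adjusted p of 0.107, 0.0712 and 0.0748 without healthy replicates 1 to 3, 0.0605, 0.054 and 0.055 without border zone replicates 1 to 3, and 0.0942 and 0.101 without ischemic replicates 1 and 3. All 5 measured genes of calcium handling and ion channels fell, over all genes and adjusted over the list alone, among them PLN, the regulator of the calcium pump (-2.87 ± 0.46), and GJA1, connexin 43 (-1.65 ± 0.28). That list was lower by camera (adjusted p = 3.63e-05, and adjusted p = 0.205 with an estimated correlation). Of 7 cardiac transcription factors 6 fell, and 6 adjusted over the list alone. MYOCD, a coactivator of muscle genes (NM_213745, chromosome 12 from 59867285 to 60022083), fell 10.6-fold (log2 fold change -3.40 ± 0.38, adjusted p = 0.00121), GATA6 had -2.63 ± 0.36 and GATA4 had -1.73 ± 0.27. The list was lower by camera (adjusted p = 2.24e-05, and adjusted p = 0.117 with an estimated correlation).

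The fetal gene programme did not rise as a group. Of its 8 measured genes 2 fell and 0 rose, and 2 fell adjusted over the list alone. MYH7 and ANKRD1 are also in the sarcomere list, so the lists are not independent. FHL1, a LIM protein of muscle, had a log2 fold change of -1.35 ± 0.31 (adjusted p = 0.0157). The list was lower by camera (adjusted p = 0.0156, and adjusted p = 0.205 with an estimated correlation). The natriuretic peptide genes did not pass, with a log2 fold change of 3.04 ± 1.34 for NPPB (adjusted p = 0.128) and 0.66 ± 1.61 for NPPA (adjusted p = 0.791). NPPB averaged 1.99 ± 3.24 RPKM in healthy, 10.6 ± 2.16 in border zone and 5.72 ± 3.4 in ischemic myocardium.

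Genes of fatty acid and oxidative metabolism fell in part. In fatty acid uptake and oxidation 9 of 17 genes fell and 0 rose, and adjusted over the list alone 9 fell and 1 rose. Besides CD36 (-3.08 ± 0.35, adjusted p = 0.00122), HADHA, a subunit of the mitochondrial trifunctional protein, had -2.11 ± 0.27 (adjusted p = 0.00167). In oxidative phosphorylation and the citrate cycle 10 of 23 genes fell and 0 rose, 12 adjusted over the list alone, such as ATP5O, a subunit of ATP synthase (-2.09 ± 0.46, adjusted p = 0.0138). The fatty acid and oxidative lists were lower by camera (adjusted p = 1.37e-05 and 9.87e-07), with adjusted p = 0.205 for each with an estimated correlation. Of 16 genes of glycolysis and the hypoxia response 8 rose and 0 fell, 9 adjusted over the list alone. LDHA, a lactate dehydrogenase subunit, rose 10.6-fold (log2 fold change 3.41 ± 0.40, adjusted p = 0.00124), hexokinase HK2 had 3.14 ± 0.40 and the hypoxia factor HIF1A had 1.39 ± 0.22 (adjusted p = 0.0033). That list was higher by camera (adjusted p = 0.0225, and adjusted p = 0.287 with an estimated correlation), and missed the threshold without ischemic replicate 3 (adjusted p = 0.052), with quantile normalization (0.0576) and with the filter at 2 RPKM (0.167). GAPDH, often used as a reference gene, had -0.33 ± 0.38 (adjusted p = 0.555), and 0.10 without healthy replicate 1. VEGFA, a vascular growth factor, had 0.90 ± 0.27 (adjusted p = 0.039), with adjusted p from 0.055 to 0.0965 without any of 8 of the libraries.

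Many inflammatory genes rose. Of 17 measured cytokine and chemokine genes 12 rose and 0 fell, 14 adjusted over the list alone. IL1A had a log2 fold change of 5.29 ± 0.43 (adjusted p = 0.000271), CXCL2 had 2.93 ± 0.27 and PTGS2, the inducible prostaglandin synthase, had 3.47 ± 0.26 (adjusted p = 0.00026). IL6 had 30 reads over the ischemic libraries and 3 over the healthy libraries, a 30.5-fold ratio with an exact 95% counting interval of 9.49 to 156. It was 46-fold (13.8 to 240) without ischemic replicate 1, 19.6-fold (5.48 to 106) without ischemic replicate 2 and at least 14.8-fold without healthy replicate 3. The chemokine CCL2 rose from 2.29 ± 1.86 to 29.1 ± 12.9 RPKM (adjusted p = 0.00413). Of 16 genes of the NF-kB pathway 11 rose and 0 fell, 12 adjusted over the list alone, with the receptor TLR4 at 3.56 ± 0.42, its adaptor MYD88 at 2.86 ± 0.43 and the adhesion molecule ICAM1 at 2.96 ± 0.51. Both lists were higher by camera (adjusted p = 6.19e-06 and 8.65e-05), with adjusted p = 0.205 for each with an estimated correlation. Interferon-stimulated genes did not pass as a list (camera adjusted p = 0.13, and 0.0424 without healthy replicate 1), with 3 of 17 higher over all genes and 0 adjusted over the list alone. At an unadjusted p under 0.05 the list had 6 higher, and limma-voom called 3. Of the 3, MX1 had 1.36 ± 0.34 (adjusted p = 0.0207), with adjusted p of 0.0622 without healthy replicate 2, 0.0681 without healthy replicate 3 and 0.0501 without ischemic replicate 1.

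Many markers of leukocytes rose in ischemic myocardium. Of 12 macrophage and monocyte genes 8 rose and 0 fell, 8 adjusted over the list alone, such as CD14, a receptor for lipopolysaccharide (4.37 ± 0.50, adjusted p = 0.00122), and the scavenger receptor MSR1 (2.92 ± 0.29, adjusted p = 0.000614). Of 5 neutrophil genes 3 rose, 4 adjusted over the list alone. S100A8, a calprotectin subunit (NM_001160271, chromosome 4 from 105091816 to 105092749), had 34 reads over the ischemic and 0 over the healthy libraries, at least 34.6-fold higher against a floor of 3 reads over the group. S100A12 was at least 52.9-fold higher, with 52 reads against 0, and the activating receptor TREM1 had 3.16 ± 0.53 (adjusted p = 0.00444). Camera gave adjusted p = 0.00434 for macrophages and 0.00639 for neutrophils, both higher, and adjusted p = 0.205 for each with an estimated correlation. The neutrophil list had a median log2 fold change of 3.16, or 5.07 with the genes absent from healthy libraries set at their bound. Of the 4 lymphocyte genes measured, too few to test, CCR7 rose, with 50 reads over the ischemic and 3 over the healthy libraries, a 50.8-fold ratio with an exact 95% counting interval of 16.4 to 255 (adjusted p = 0.0111), while CD2, CD8A and NKG7 did not pass. GPR84, a receptor of myeloid cells, was at least 54.9-fold higher, with 54 reads against 0. Without healthy replicate 3, the deepest of its group, the bounds of S100A8, S100A12, GPR84 and CCR7 were 16.8-fold, 25.7-fold, 26.6-fold and 24.7-fold. Without ischemic replicate 1 the bound of S100A12 and the ratio of CCR7 (8.16 to 159) were 29.2-fold each. CCR1, a chemokine receptor, rose 49.9-fold and ARG1, arginase 1, rose 77.8-fold.

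Markers of the vessel wall went in both directions. Of 10 endothelial genes 4 rose and 1 fell, and the same numbers held adjusted over the list alone. PECAM1, the adhesion molecule CD31, rose 1.68-fold (adjusted p = 0.0169, and 0.0622 without healthy replicate 2), and the fall was that of PROX1 (-1.78 ± 0.20), which is also in the cardiac transcription factor list. The endothelial list had camera adjusted p = 0.13, and passed as higher with pig as a block (adjusted p = 0.0466, and adjusted p = 0.215 with an estimated correlation) and without a filter (0.0288). Of 6 smooth muscle and pericyte genes, TAGLN, transgelin, rose (1.38 ± 0.18, adjusted p = 0.00175), and MYOCD and PLN, which the heart muscle lists also hold, fell, with 1 higher and 2 lower adjusted over the list alone as well (camera adjusted p = 0.167). The smooth muscle list passed as lower by limma-voom (adjusted p = 0.0291), with thinned reads (0.047) and by fry (0.0444). HBB, a haemoglobin gene, rose with 2.65 ± 0.78 (adjusted p = 0.0378), but had an adjusted p of 0.0965 and 0.115 without healthy replicates 1 and 3, 0.0577 without border zone replicate 1, and 0.111 and 0.0719 without ischemic replicates 1 and 2. TFRC, the other erythroid gene measured, had -0.79 ± 0.33 (adjusted p = 0.112). WT1, the only epicardial gene measured, had -0.17 ± 0.30, and of the cell cycle genes CCND2 had 0.01 ± 0.29 and CCND3 1.14 ± 0.44 (adjusted p = 0.0861). None of the 6 adipocyte genes passed in limma (camera adjusted p = 0.338), with 1 higher at an unadjusted p under 0.05 and 1 higher by limma-voom.

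Many matrix and protease genes rose. Of 15 fibroblast and matrix genes 9 rose and 0 fell, 10 adjusted over the list alone, including VCAN, the proteoglycan versican (2.89 ± 0.26, adjusted p = 0.000506), and TNC, tenascin C (2.72 ± 0.45, adjusted p = 0.00412). POSTN, periostin, did not pass (1.41 ± 0.50, adjusted p = 0.0681), and passed with pig as a block (adjusted p = 0.0206). TIMP1, an inhibitor of metalloproteases (NM_213857, chromosome X from 47372604 to 47375637), rose from 0.202 ± 0.35 to 29.1 ± 12.9 RPKM (log2 fold change 7.14 ± 0.75, adjusted p = 0.000895). Of 12 genes of matrix proteases and the plasminogen system 10 rose and 0 fell, 11 adjusted over the list alone, such as PLAT, tissue plasminogen activator (2.07 ± 0.19, adjusted p = 0.000506), and the cathepsin gene CTSB (2.19 ± 0.36). Of 16 TGF-beta and wound response genes 7 rose and 0 fell, 8 adjusted over the list alone, with the transcription factor RUNX1 at 3.15 ± 0.30 (adjusted p = 0.000528). Camera gave adjusted p = 0.00584 for matrix, 9.82e-05 for proteases and 0.0121 for TGF-beta, all higher, and adjusted p = 0.205 for each with an estimated correlation. The matrix list had an adjusted p of 0.0551 without ischemic replicate 2.

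Stress responses rose in part. Of 16 immediate early genes 6 rose and 1 fell, 8 and 1 adjusted over the list alone. FOS, a subunit of the AP-1 factor, rose 8.28-fold from 7.13 ± 0.545 to 62 ± 19.3 RPKM (adjusted p = 0.00141), and MYC had 2.55 ± 0.40. The fall was that of NR4A3 (-1.45 ± 0.35, adjusted p = 0.0194), with adjusted p of 0.0553 and 0.0679 without healthy replicates 1 and 2 and 0.0575 without ischemic replicate 3. Of 10 genes of the unfolded protein response 5 rose and 0 fell, 8 adjusted over the list alone, such as CALR, the chaperone calreticulin (1.98 ± 0.38, adjusted p = 0.00847). These lists were higher by camera, with adjusted p = 0.0191 for immediate early genes and 0.00584 for the unfolded protein response, and adjusted p = 0.205 for each with an estimated correlation. Quantile normalization ended the call of the immediate early list (adjusted p = 0.113). Of 10 heat shock genes 5 rose and 0 fell, 7 adjusted over the list alone, with HSPH1 at 2.07 ± 0.39 and DNAJB1 at 1.66 ± 0.30, while the list itself missed the threshold (camera adjusted p = 0.0594). It passed as higher without healthy replicate 1 (adjusted p = 0.0191), border zone replicate 2 (0.0481), ischemic replicate 1 (0.0405) or ischemic replicate 3 (0.0282), without a filter (0.0186), in a fit on these 2 groups alone (0.0485), with the mean over the positions of a gene (0.0202), by limma-voom (0.0292) and by fry (0.0016). Of 8 p53 targets 1 rose, PMAIP1 (2.12 ± 0.44, adjusted p = 0.0109), also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.514). Of 14 NRF2 targets 3 rose and 1 fell, likewise adjusted over the list alone, with glutathione peroxidase GPX1 higher (2.99 ± 0.44) and catalase CAT lower (-1.54 ± 0.28), and the list did not pass (camera adjusted p = 0.576). Of 25 ribosomal protein genes 13 rose and 0 fell, 19 adjusted over the list alone, with a median log2 fold change of 1.09. Their positions span 1000 to 10000 bp, and the median of all positions was 0.70 from 1000 to 3000 bp and 0.47 from 3000 to 10000 bp. That list was higher by camera (adjusted p = 2.5e-05, and adjusted p = 0.205 with an estimated correlation). These genes have processed copies elsewhere in the genome, and how reads with several positions were counted is not given in the sources used here.

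**Figure D2:**
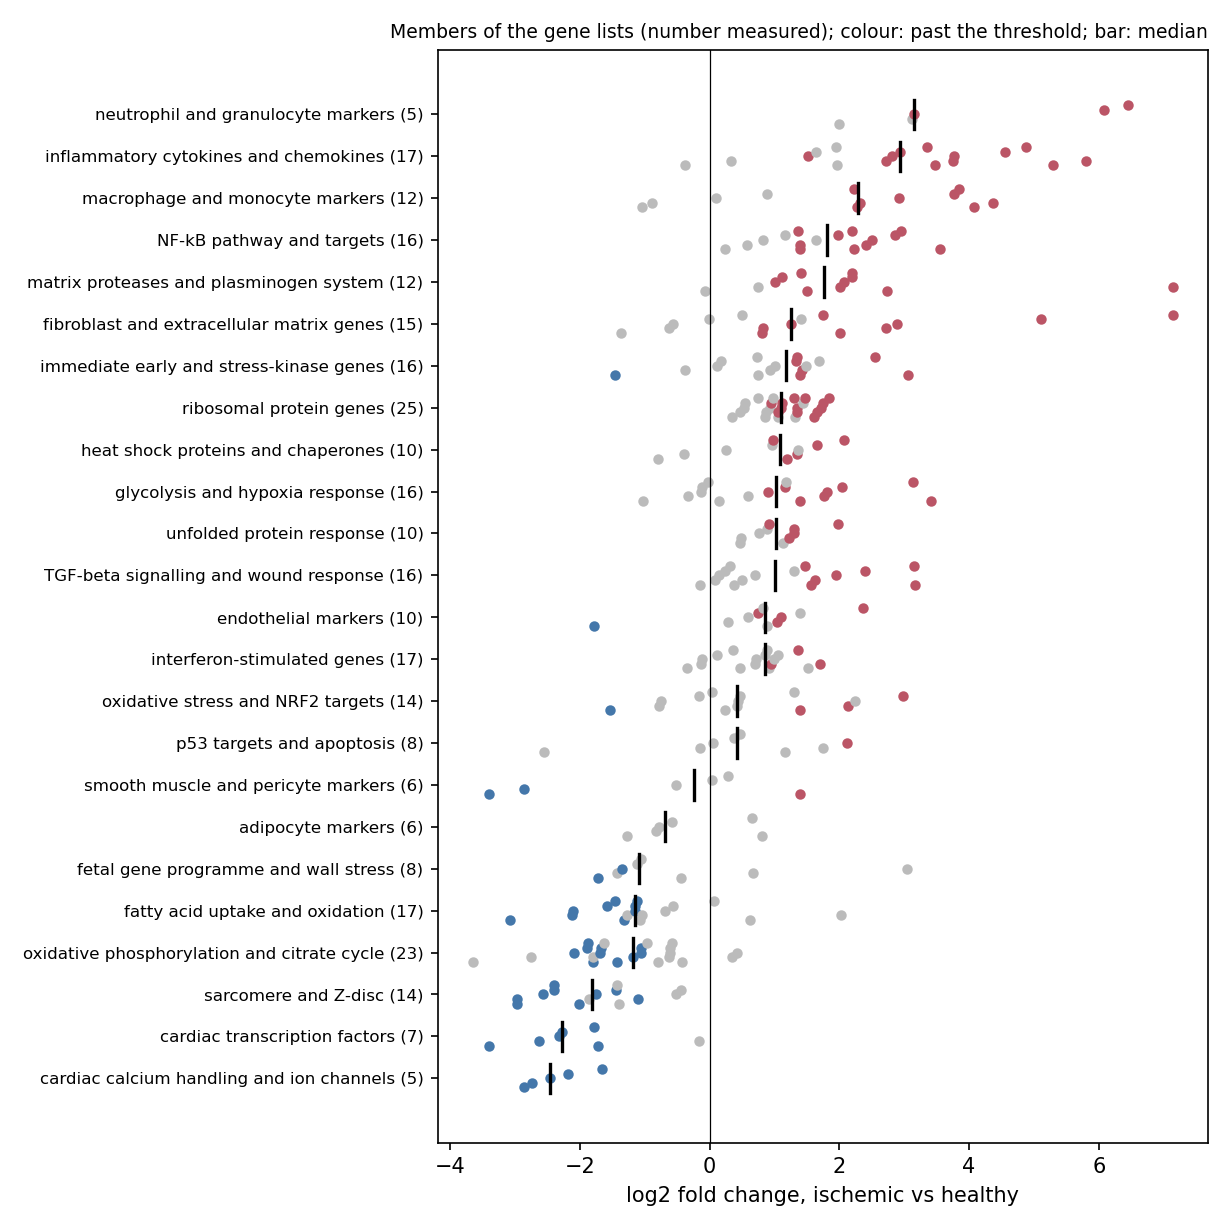
Log2 fold change of each measured member of the coding gene lists in ischemic against healthy myocardium (n = 3 each), with members past an adjusted p of 0.05 coloured and a bar at the median of each list. Medians run from -2.46 for calcium handling to 3.16 for neutrophil genes, and the sarcomere median is -1.81.

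Non-coding positions are mostly microRNA loci of about 79 bp, where few reads fall. Of 72 non-coding positions tested 3 were higher and 5 lower in ischemic than in healthy myocardium, and 5 of these 8 were microRNA loci. The median SE of non-coding positions was 2 log2 units, against 0.37 for coding positions. MIR1, a microRNA of heart and skeletal muscle (NR_035375, chromosome 17 from 69285393 to 69285500), had 0 reads in the ischemic and 34 in the healthy libraries, at least 3.71-fold lower (adjusted p = 0.00124). MIR208B, which lies inside the span of MYH7 (NR_038551, chromosome 7 from 81071323 to 81071402), had 2 reads against 98, a 16.1-fold lower level with an exact 95% counting interval of 4.33 to 134. MIR29B-1 had 11 reads against 0, at least 11.2-fold higher, while MIR29C had 0 against 15, at least 1.64-fold lower. MIR219A is among the 5 lower positions (adjusted p = 0.0301), but its healthy level lies under the floor of the ischemic libraries, so a difference was not detectable at this depth. Its call ended without healthy replicates 1 to 3 (adjusted p of 0.0715, 0.084 and 0.0701) or ischemic replicates 1 to 3 (0.0726, 0.0598 and 0.0709). MIR133A-1, which did not pass, lies under the same floor. Without ischemic replicate 1 the bound of MIR1 was 1.81-fold, MIR208B was at least 5.21-fold lower and MIR29C was not detectably different. Without healthy replicate 3 the bounds of MIR29B-1 and MIR29C were 5.43-fold and 2.7-fold. MIR21, an injury-related microRNA, had 4, 0 and 18 reads in the ischemic and 1, 0 and 0 in the healthy libraries, and did not pass (adjusted p = 0.251). Its pooled reads gave a 67.1-fold ratio with an exact 95% counting interval of 10.8 to 2770. In the list of muscle microRNA loci 3 of 11 fell and 1 rose, as adjusted over the list alone. It was lower by camera (adjusted p = 0.01, and adjusted p = 0.205 with an estimated correlation), with a median log2 fold change of -4.48, or -1.26 with loci at 0 set at their bound, and it missed the threshold by limma-voom (adjusted p = 0.184) and with thinned reads (0.0661). None of 10 injury microRNA loci passed in limma (camera adjusted p = 0.585), with 1 higher at an unadjusted p under 0.05 and 2 higher by limma-voom, and the list has a median of -0.17, a mean of 0.32 and 1.61 as the median with loci at 0 set at their bound. Among the remaining genes with the largest falls, MLPH had 0 reads in the ischemic libraries and was at least 9.72-fold lower than in healthy ones, or 4.73-fold without ischemic replicate 1, and the neuropeptide gene CCK fell from 10.5 ± 5.13 to 0.571 ± 0.989 RPKM (adjusted p = 0.0151, and 0.0542 without healthy replicate 2).

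The comparison of border zone with healthy myocardium asks what changed next to the infarct. Genes of the cytokine, macrophage, neutrophil and matrix lists rose there as well, 9 of 17, 5 of 12, 2 of 5 and 5 of 15, and 5 positions fell. IL1B rose 51.3-fold, from 0.209 ± 0.0485 to 16 ± 4.11 RPKM (mean ± SD, n = 3 each), and SPP1 rose 19.8-fold, from 0.124 ± 0.0781 to 4.38 ± 1.83 RPKM. TIMP1 averaged 15.4 ± 4.47 RPKM in the border zone, with a log2 fold change of 6.29 ± 0.75 (adjusted p = 0.00301). Of 2384 positions 138 were higher and 5 lower (limma), while 510 had an unadjusted p under 0.05, where chance would give 119, and each of the 143 moved in 1 direction in 3 of 3 pigs. They belong to 136 genes, 131 higher and 5 lower. With pig as a block 192 positions were higher and 13 lower. The median log2 fold change of all positions was 0.22. The count fell to 63, 42 and 65 without healthy replicates 1 to 3, and to 36 and 37 without border zone replicates 1 and 3. It was 86 with a pseudocount of 0.5, 95 without a filter, 76 with a filter at 2 RPKM, 85 with quantile normalization, 84 with libraries scaled to the same median and 296 by limma-voom.

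Some inflammatory genes rose in the border zone. Of 17 cytokine and chemokine genes 9 rose and 0 fell, 11 adjusted over the list alone, with IL1A at 5.02 ± 0.43 (adjusted p = 0.000588), CXCL2 at 2.47 ± 0.27 and PTGS2 at 1.97 ± 0.26 (adjusted p = 0.00478). IL1B2, an interleukin 1 beta paralogue, had 271 reads in the border zone and 0 in healthy libraries, at least 89.9-fold higher. Of 16 NF-kB genes 5 rose and 0 fell, 8 adjusted over the list alone, with TLR4 at 2.99 ± 0.42 (adjusted p = 0.00572). Of 12 macrophage genes 5 rose and 0 fell, 9 adjusted over the list alone, with MSR1 at 2.68 ± 0.29 (adjusted p = 0.00195). Of 5 neutrophil genes 2 rose and 0 fell, 3 adjusted over the list alone. S100A12 had 46 reads against 0, at least 15.3-fold higher (adjusted p = 0.00271), and S100A8 had 20 against 0, at least 6.64-fold higher, without passing (adjusted p = 0.163). GPR84 was at least 24.2-fold higher, with 73 reads against 0, and ARG1 rose 41.4-fold (adjusted p = 0.000899). Camera found each of these lists higher, with adjusted p of 4.16e-07 for cytokines, 1.96e-05 for the NF-kB pathway, 1.96e-05 for macrophages and 0.0049 for neutrophils. With an estimated correlation these became adjusted p = 0.235, 0.269, 0.235 and 0.269. Of the 4 lymphocyte genes CCR7 rose, with 88 reads against 3, a 29.2-fold ratio with an exact 95% counting interval of 9.67 to 144 (adjusted p = 0.0397), a call lost with pig as a block (adjusted p = 0.0514) and without each library in turn (adjusted p from 0.0505 to 0.168). Without healthy replicate 3 the bounds of IL1B2, S100A12, S100A8, GPR84 and CCR7 were 43.6-fold, 7.41-fold, 3.22-fold, 11.8-fold and 14.2-fold.

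Some matrix, protease, hypoxia and immediate early genes rose in the border zone too. Of 15 matrix genes 5 rose and 0 fell, 5 adjusted over the list alone, with VCAN at 1.90 ± 0.26 (adjusted p = 0.00542). Of 12 protease genes 4 rose and 0 fell, 7 adjusted over the list alone, TIMP1 among them. These lists were higher by camera (adjusted p = 0.00578 and 0.00334), with adjusted p = 0.235 for each with an estimated correlation. Of 16 TGF-beta genes 2 rose, 4 adjusted over the list alone, with RUNX1 at 2.91 ± 0.30 (adjusted p = 0.00156), and the list did not pass by camera (adjusted p = 0.108) but did by fry (0.0102). Of 16 genes of glycolysis and hypoxia 4 rose and 0 fell, 5 adjusted over the list alone, with LDHA at 2.90 ± 0.40 (adjusted p = 0.00522). That list missed the threshold (camera adjusted p = 0.0527) and passed as higher with pig as a block (adjusted p = 0.0392, and adjusted p = 0.39 with an estimated correlation), with a pseudocount of 0.02 (0.049), without a filter (0.0194), with quantile normalization (0.0133), with the mean over the positions of a gene (0.0291), by limma-voom (0.0266), by fry (0.0102), and without ischemic replicate 2 (0.0492) or 3 (0.0406). Of 16 immediate early genes 2 rose and 0 fell, 6 adjusted over the list alone, with FOS rising 6.84-fold to 52.1 ± 21 RPKM (adjusted p = 0.00478). The list was higher by camera (adjusted p = 0.0156, and adjusted p = 0.269 with an estimated correlation), but not without border zone replicate 3 (adjusted p = 0.0568). None of 25 ribosomal protein genes passed in limma, with 4 higher at an unadjusted p under 0.05 and 1 by limma-voom. The ribosomal list was higher by camera (adjusted p = 0.0355, and adjusted p = 0.541 with an estimated correlation), but not with libraries scaled to the same median (0.0801), nor without healthy replicate 2 (0.0731), healthy replicate 3 (0.318) or border zone replicate 3 (0.0699), nor by the self-contained test fry (0.0768).

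Of the lists of muscle, fatty acid and oxidative genes 1 member passed in the border zone, CD36 (limma), while camera placed 5 of these 6 lists lower. None of 14 sarcomere genes passed, over all genes or adjusted over the list alone, with 6 lower at an unadjusted p under 0.05 and 5 lower by limma-voom. Camera placed the list lower (adjusted p = 6.26e-06, and adjusted p = 0.269 with an estimated correlation). None of 5 calcium handling genes passed over all genes, while all 5 were lower adjusted over the list alone and 4 by limma-voom. ATP2A2 had a log2 fold change of -1.08 ± 0.35 (adjusted p = 0.124) and passed with pig as a block (adjusted p = 0.0447). That list was lower by camera (adjusted p = 7.26e-05, and adjusted p = 0.261 with an estimated correlation). None of 7 cardiac transcription factors passed over all genes, with 1 lower adjusted over the list alone, 4 at an unadjusted p under 0.05 and 3 by limma-voom. That list was lower by camera (adjusted p = 0.000597, and adjusted p = 0.235 with an estimated correlation). Of 17 fatty acid genes CD36 fell (-1.51 ± 0.35, adjusted p = 0.0448), with 2 lower adjusted over the list alone, and the call of CD36 was lost without any of 7 libraries (adjusted p from 0.057 without border zone replicate 2 to 0.178 without border zone replicate 1). None of 23 oxidative genes passed, with 0 adjusted over the list alone, 3 lower at an unadjusted p under 0.05 and 0 by limma-voom. Camera gave adjusted p = 1.96e-05 and 6.46e-07 for these lists, both lower, and adjusted p = 0.235 and 0.269 with an estimated correlation. By the self-contained test fry the sarcomere and oxidative lists (adjusted p = 0.148 each), calcium handling (0.0526) and fatty acids (0.0529) missed the threshold, and transcription factors passed (0.0102). The fetal list did not pass (camera adjusted p = 0.169), with a median log2 fold change of -0.06, a mean of 0.45 and a test in the lower direction, and NPPB had 4.16 ± 1.34 (adjusted p = 0.124). The other falls were PRKAA2, a catalytic subunit of the energy sensor AMPK (-1.13 ± 0.23, adjusted p = 0.0337), the transcript NM_213966, which carries no symbol (-1.19 ± 0.28, adjusted p = 0.0476), and a pair of short positions of GRB10 and IGFBP5, of 145 and 333 bp, which were named after their values were seen. Longer positions of GRB10 and IGFBP5, of 129933 and 2341 bp, did not pass (0.12 and -0.55, adjusted p = 0.776 and 0.48). The calls of PRKAA2 and NM_213966 were lost without border zone replicate 1 (adjusted p = 0.127 and 0.178), border zone replicate 3 (0.137 and 0.178) and any healthy library (0.0621 to 0.152), and that of NM_213966 also without ischemic replicates 1 and 3 (0.0534 and 0.0689).

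No other list changed in the border zone by camera except the muscle microRNA loci. Heat shock genes (adjusted p = 0.685), the unfolded protein response (0.146, and 0.0205 without healthy replicate 1), interferon-stimulated genes (0.909), endothelium (0.685), smooth muscle (0.24, and 0.0462, lower, with thinned reads), p53 targets (0.458), NRF2 targets (0.909), adipocyte genes (0.236) and injury microRNA loci (0.685) did not pass. In the endothelial list the median and mean log2 fold changes were 0.07 and 0.29, while the test ran in the lower direction. Single members rose in a pair of these lists, GPX1 among NRF2 targets (2.49 ± 0.44, adjusted p = 0.0182) and PMAIP1 among p53 targets (2.07 ± 0.44, adjusted p = 0.0353). Without border zone replicate 3 their adjusted p were 0.078 and 0.142, and without border zone replicate 1 they were 0.093 and 0.122. The calls also ended without healthy replicate 2, at 0.0796 and 0.0602. GPX1 further had 0.0632 without healthy replicate 3, and PMAIP1 had 0.0577 without healthy replicate 1, 0.0533 without ischemic replicate 1 and 0.0503 without ischemic replicate 3. The muscle microRNA list was lower by camera (adjusted p = 0.0206, and adjusted p = 0.318 with an estimated correlation), with 0 of 11 members past the threshold in limma or by limma-voom and 1 lower at an unadjusted p under 0.05. The call ended with quantile normalization (adjusted p = 0.339), with libraries scaled to the same median (0.207), without healthy replicate 3 (0.143), without border zone replicate 1 (0.175) and by fry (0.416). Of the 72 non-coding positions 1 was higher, MIR103-2, with 17 reads in the border zone and 0 in both other groups, at least 5.64-fold higher than in healthy myocardium (adjusted p = 0.00195). That bound was 3.22-fold and 11.1-fold without border zone replicates 1 and 2 and 2.74-fold without healthy replicate 3. HBB, TFRC, WT1, CCND2 and CCND3, from lists too small to test, did not pass, with log2 fold changes of -0.73, -0.57, -0.33, 0.08 and 0.27.

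The border zone shared most of its higher genes with ischemic myocardium. Log2 fold changes against healthy myocardium correlated with r = 0.72 across 2384 positions, which are not independent, against 0.51 (range 0.4 to 0.6) in 100 simulations of unchanged groups with the same shared healthy libraries. The covariance was 1.11 against 0.267 in the simulations, a difference of 0.844. The simulations drew each position independently. Positions that vary together within a library would widen the simulated ranges, so these do not bound what the shared healthy libraries alone can give. Of the 442 positions higher in ischemic and the 138 higher in border zone myocardium 133 were higher in both, and of the 217 and 5 lower positions 4 were lower in both. The 133 became 59, 38 and 61 without healthy replicates 1 to 3, and 33 and 34 without border zone replicates 1 and 3. Both comparisons use the same 3 healthy libraries, which are too few to split between them. Over the 442 positions higher in ischemic myocardium the median log2 fold change was 1.57 there and 1.06 in the border zone, and over the 217 lower positions it was -1.85 there and -0.65 in the border zone. These positions were selected by their change in ischemic myocardium, so the shared healthy libraries alone would bring a border zone median of the same sign. The size of that share was not simulated, so these medians do not measure a border zone change by themselves.

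**Figure D3:**
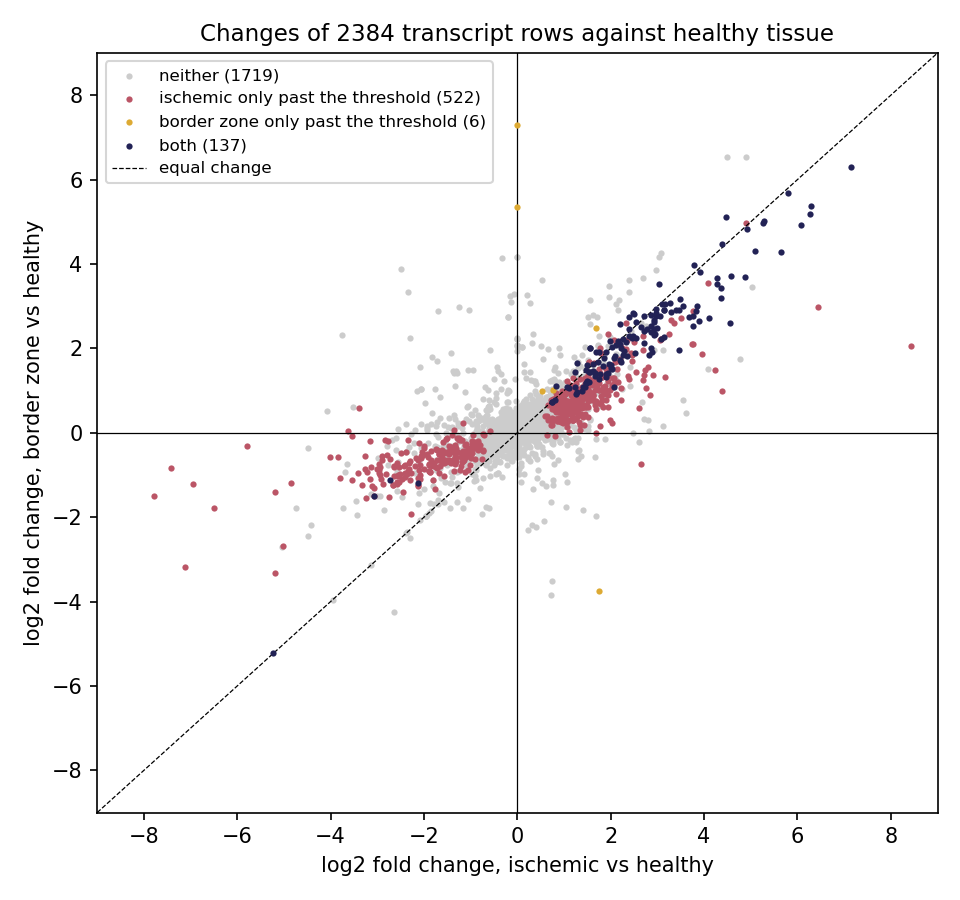
Log2 fold change of each of 2384 positions in border zone (vertical axis) and ischemic myocardium (horizontal axis) against healthy myocardium, coloured by the comparison in which it passed. The 133 positions higher in both lie at the upper right and 4 positions are lower in both, with r = 0.72.

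The comparison of ischemic with border zone myocardium asks what sets the infarct apart from its surroundings, and it gave few calls. CSRP3 fell 4.68-fold, from 7.27 ± 1.07 to 1.49 ± 0.335 RPKM (mean ± SD, n = 3 each, adjusted p = 0.0173), and MYOCD fell 5.45-fold, from 1.63 ± 0.483 to 0.24 ± 0.184 RPKM (adjusted p = 0.041). SMYD1, a histone methyltransferase of muscle, had -2.70 ± 0.44 (adjusted p = 0.0446, and 0.0608 with pig as a block). PTGS2 rose 2.82-fold, from 1.79 ± 0.0702 to 5.26 ± 0.741 RPKM (adjusted p = 0.0472). Of 2384 positions 4 were higher and 23 lower (limma), while 373 had an unadjusted p under 0.05, where chance would give 119, and each moved in 1 direction in 3 of 3 pigs. They belong to 26 genes, 4 higher and 22 lower. Besides PTGS2, the higher positions were short or partial ones of PTMA, ADAM10 and IGFBP5, named after their values were seen. Longer positions did not pass, with -0.28 (lower in 3 of 3 pigs, adjusted p = 0.685) and 0.23 (adjusted p = 0.719) for ADAM10 at 51173 and 46768 bp and 0.93 (adjusted p = 0.304) for IGFBP5 at 2341 bp. The calls are fragile. No position passed without healthy replicate 3 or without border zone replicate 3 (limma), where 334 and 300 had an unadjusted p under 0.05 and limma-voom called 81 and 58. The call of CSRP3 ended without healthy replicate 3 (adjusted p = 0.0537), border zone replicates 1 to 3 (0.0546, 0.0557 and 0.0673) or ischemic replicate 3 (0.0724). That of MYOCD ended without any library except ischemic replicate 2, with adjusted p up to 0.141, and that of PTGS2 without any library except healthy replicate 2, with adjusted p up to 0.172. That of SMYD1 ended without healthy replicates 1 and 3 (0.0654 and 0.0722), border zone replicates 1 to 3 (0.111, 0.156 and 0.103) or ischemic replicate 3 (0.0847). The count was 2 and 10 without healthy replicates 1 and 2, 3 and 4 without border zone replicates 1 and 2, 1 without ischemic replicate 3, and 5 with quantile normalization, 8 with libraries scaled to the same median, 10 with a pseudocount of 0.5, 3 without a filter and 92 by limma-voom.

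Lists of heart muscle genes were lower in ischemic than in border zone myocardium by camera. Of 14 sarcomere genes 2 fell, CSRP3 and ACTN2 (-2.02 ± 0.36, adjusted p = 0.0478, and 0.0738 to 0.172 without any library except ischemic replicate 2), and the same 2 adjusted over the list alone. Of 7 cardiac transcription factors MYOCD fell, with 4 lower adjusted over the list alone. None of 5 calcium handling genes passed over all genes, with 4 lower adjusted over the list alone, 4 at an unadjusted p under 0.05 and 3 by limma-voom. Camera gave adjusted p = 0.000197 for the sarcomere, 5.94e-05 for transcription factors and 0.000398 for calcium handling. With an estimated correlation these became adjusted p = 0.371, 0.118 and 0.276. Of 17 fatty acid and 23 oxidative genes 0 passed over all genes, with 3 and 0 lower adjusted over the list alone, 5 and 7 at an unadjusted p under 0.05 and 2 and 1 by limma-voom. Of 8 fetal genes 0 passed, with 2 lower adjusted over the list alone, 2 at an unadjusted p under 0.05 and 1 by limma-voom. These lists were lower by camera, with adjusted p of 0.000887, 0.004 and 0.0129, which became adjusted p = 0.276, 0.416 and 0.276 with an estimated correlation. By the self-contained test fry transcription factors (adjusted p = 0.00159) and the fetal list (0.0475) passed, and the sarcomere (0.0779), calcium handling (0.0516), fatty acid (0.0516) and oxidative (0.19) lists did not. The oxidative list missed the threshold without border zone replicate 2 (0.0952) and the fetal list without ischemic replicate 1 (0.0723).

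Lists of stress, inflammatory, matrix and ribosomal genes were higher in ischemic than in border zone myocardium by camera, almost without single calls. PTGS2 was the only member called in them (limma), in the cytokine list (camera adjusted p = 0.004, and adjusted p = 0.371 with an estimated correlation). Adjusted over the list alone, 2 protease genes, 2 endothelial genes, 1 unfolded protein response gene and 1 ribosomal protein gene were higher, and 1 endothelial gene was lower. At an unadjusted p under 0.05 these lists had 5, 3, 3 and 10 higher members, and limma-voom called 2, 0, 0 and 1. The endothelial list also had 1 lower member at an unadjusted p under 0.05 and by limma-voom. Camera gave adjusted p of 0.000398, 0.0127, 0.000887 and 6.2e-07, which became 0.276, 0.397, 0.276 and 0.276 as adjusted p with an estimated correlation. Of the 10 heat shock genes 5 were higher at an unadjusted p under 0.05 and 1 by limma-voom, and the list was higher by camera (adjusted p = 0.004, and adjusted p = 0.276 with an estimated correlation), but not with quantile normalization (0.0983) or without ischemic replicate 2 (0.0618). The matrix list (camera adjusted p = 0.0187), TGF-beta list (0.0289), interferon list (0.0289), hypoxia list (0.0381) and NF-kB list (0.039) were higher with 0 members called over all genes or adjusted over the list alone. With an estimated correlation they had adjusted p = 0.276, 0.371, 0.467, 0.416 and 0.483. At an unadjusted p under 0.05 they had 2, 3, 2, 1 and 0 higher members, and limma-voom called 1 in the matrix list. Of the lists called higher by camera, proteases (adjusted p = 0.0475) and no other passed by the self-contained test fry. Quantile normalization ended the hypoxia (adjusted p = 0.62), NF-kB (0.0968), TGF-beta (0.0626) and matrix (0.0501) calls by camera. Thinned reads ended the hypoxia (adjusted p = 0.0604), NF-kB (0.132), TGF-beta (0.0659) and interferon (0.0727) calls. Each of the calls of the matrix, TGF-beta, interferon, hypoxia and NF-kB lists also ended without single libraries. For the matrix list these were border zone replicate 1 (adjusted p = 0.141) and ischemic replicate 2 (0.225), and for TGF-beta border zone replicate 2 (0.0914) and ischemic replicate 3 (0.117). For the interferon list they were border zone replicates 2 and 3 (0.0682 and 0.0741) and ischemic replicate 1 (0.179). For the hypoxia list they were border zone replicates 1 and 2 (0.0622 and 0.0682) and ischemic replicate 3 (0.341), and for NF-kB border zone replicate 2 (0.32) and ischemic replicates 1 and 3 (0.22 and 0.0832). The neutrophil list missed the threshold (camera adjusted p = 0.061) and passed as higher with pig as a block (adjusted p = 0.0488, and adjusted p = 0.372 with an estimated correlation) and without border zone replicate 1 (0.0268), border zone replicate 3 (0.0318) or ischemic replicate 2 (0.00737), with a pseudocount of 0.5 (0.0331) and by limma-voom (0.0258). Immediate early genes (0.26), macrophages (0.526), smooth muscle (0.285, but lower by limma-voom, 0.036, with MYOCD lower over all genes and 1 higher and 2 lower adjusted over the list alone), p53 targets (0.936), NRF2 targets (0.385), adipocyte genes (0.923), muscle microRNA loci (0.0859, but 0.00444 without border zone replicate 1 and 0.0263 without ischemic replicate 3) and injury microRNA loci (0.198) did not pass by camera. Of the non-coding positions 2 were lower, MIR1 with 0 reads against 32, 30 of them in border zone replicate 2, at least 3.48-fold lower, and MIR103-2 with 0 against 17, at least 1.85-fold lower. Without border zone replicate 2 a difference of MIR1 was not detectable at this depth, and its bound was 1.69-fold without ischemic replicate 1. The bound of MIR103-2 was 1.06-fold and 3.62-fold without border zone replicates 1 and 2, and without ischemic replicate 1 no difference was detectable. The call of MIR1 ended without healthy replicates 1 to 3 (adjusted p of 0.0592, 0.0527 and 0.0565), border zone replicate 3 (0.0673) or ischemic replicate 3 (0.0847). That of MIR103-2 ended without healthy replicate 3 (0.0537), border zone replicates 1 and 3 (0.0639 and 0.0673) or ischemic replicate 3 (0.0674). Of the small lists 0 members passed over all genes, and HBB had 3.38 ± 0.78 (adjusted p = 0.0988).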

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

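The tests with thinned reads, by limma-voom, without the 2 shallowest libraries, on 1 position per gene (highest mean RPKM or longest span) and without positions under 300 bp were chosen after seeing the data. So was the longest position as the 1 that stands for a gene, in place of the position of highest mean RPKM. With the latter the TGF-beta list missed the threshold in ischemic against healthy myocardium (adjusted p = 0.0523), the hypoxia, TGF-beta and NF-kB lists missed it in ischemic against border zone myocardium (0.114, 0.194 and 0.0514), and the heat shock list in ischemic against healthy (0.0169) and the hypoxia list in border zone against healthy myocardium (0.0274) passed. Of 98 named genes that passed in ischemic against healthy myocardium, 98 kept their call with pig as a block and with other pseudocounts, 87 under both scalings, 94 by limma-voom, 85 with thinned reads, 74 without each library in turn and 26 without each pig in turn. Of 41 in border zone against healthy myocardium 39 kept it with the block, 31 with other pseudocounts, 27 under both scalings, 39 by limma-voom, 25 with thinned reads, 17 without each library and 3 without each pig. Of 10 in ischemic against border zone myocardium 8 kept it with the block, 3 with other pseudocounts, 2 under both scalings, 8 by limma-voom, 2 with thinned reads, and 0 without each library or without each pig. With pig as a block 752, 205 and 29 positions passed in ischemic against healthy, border zone against healthy and ischemic against border zone myocardium, among them 626 of the 659, 133 of the 143 and 18 of the 27, and 7, 1 and 2 non-coding positions passed. Among the named genes and lists 429 results kept their side of the threshold with the block, 20 came to pass and 4 ceased to. The calls of all lists ended with an estimated correlation, where 0 passed in each comparison by camera. Leaving out a library can leave 2 in a group, and leaving out a pig leaves 2 in each, with the spread pooled over groups. Leaving out the 2 shallowest libraries, ischemic replicates 2 and 3, leaves 1 ischemic library, so no counts are given for that setting. Depth limits positions with few reads. The median kept position held 16 reads in the shallowest library, and a group at 0 gives a bound against 3 reads over the group.

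Of the 659 positions that changed between ischemic and healthy myocardium, the count was 346 with a filter at a mean of 2 RPKM, which leaves 859 to test, and 92 to 698 when single libraries or pigs were left out. The 143 of border zone against healthy myocardium became 86 with a pseudocount of 0.5, 95 with no filter, 76 with the filter at 2 RPKM, 85 with quantile normalization, 84 with libraries scaled to the same median, 296 by limma-voom, 84 with thinned reads, and 10 to 174 when libraries or pigs were left out. The 27 of ischemic against border zone myocardium became 10 with a pseudocount of 0.5, 3 with no filter, 5 with quantile normalization, 8 with libraries scaled to the same median, 1 in a fit on these 2 groups alone, 6 with the mean over the positions of a gene, 6 with the position of highest mean RPKM, 92 by limma-voom, 7 with thinned reads, and 0 to 39 when libraries or pigs were left out. The 0 came without healthy replicate 3, without border zone replicate 3 or without pig 3 (limma). At an unadjusted p under 0.05 there were 334 and 300 without these libraries, and 81 and 58 by limma-voom. Of lists, 18, 14 and 17 passed in the 3 comparisons, against 11, 9 and 7 with the filter at 2 RPKM, 0, 0 and 0 with an estimated correlation, and 20, 10 and 3 by the self-contained test (fry), which ended 6 of the 14 calls in border zone against healthy myocardium (sarcomere, calcium handling, fatty acids, oxidative genes, ribosomal proteins and muscle microRNA loci) and 14 of the 17 in ischemic against border zone myocardium. Non-coding positions numbered 8, 1 and 2, and ranged over 2 to 8, 0 to 4 and 0 to 3 when libraries or pigs were left out, with 1 in ischemic against border zone myocardium with no filter. The 133 positions higher in both comparisons with healthy myocardium ranged over 9 to 157, with 9 without pig 1 and 157 without ischemic replicate 2. ATP5H, a subunit of ATP synthase, had 0 reads in ischemic and 25 in healthy libraries at its longest position, at least 2.73-fold lower. At the position of highest mean RPKM it had a log2 fold change of 2.72 (adjusted p = 0.207). Leaving out libraries did not only lower the counts, since without ischemic replicate 2 they were 698, 174 and 39 in the 3 comparisons. Apart from the filter at 2 RPKM and the estimated correlation, whose construction lowers the counts, the cause was not tested.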

Other observations

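Tests chosen only after the result was seen are those on cell mixture, the test of mature RNA, and the choice of the genes in this paragraph, which lie outside the fixed rule and were chosen after their values were seen. In ischemic against healthy myocardium (limma, n = 3 each) AREG and HBEGF, ligands of the EGF receptor, rose 21-fold (log2 fold change 4.39 ± 0.32, adjusted p = 0.00026) and 19.4-fold (4.28 ± 0.34, adjusted p = 0.000271). In the border zone they rose 22.1-fold (adjusted p = 0.000327) and 11.5-fold (adjusted p = 0.00129), each higher in 3 of 3 pigs. THBD, thrombomodulin, rose 24-fold (adjusted p = 0.00167), and the inflammasome gene NLRP3 rose 7.66-fold (adjusted p = 0.00235). The ubiquitin ligase genes TRIM63 and FBXO32, which are active in muscle wasting, fell 5.07-fold and 4.1-fold (adjusted p = 0.0033 for each). DMD, dystrophin, and SGCA, a sarcoglycan of the same complex, fell 5.26-fold (adjusted p = 0.00245) and 5.23-fold (adjusted p = 0.00102). PFKM, a glycolytic gene of muscle, fell 7.59-fold (adjusted p = 0.00296). LDHB, a lactate dehydrogenase subunit, fell 4.9-fold (adjusted p = 0.00687), while LDHA, another subunit, rose. The potassium and sodium pump subunit ATP1B1 fell 3.85-fold (adjusted p = 0.00108) and the phosphodiesterase PDE3A 8.66-fold (adjusted p = 0.00063). Each of the genes of this paragraph moved in its direction in 3 of 3 pigs. These 12 genes kept an adjusted p under 0.05 in ischemic against healthy myocardium without each library in turn, with a highest value of 0.0278 for LDHB without healthy replicate 2.

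Many muscle genes fell and many leukocyte genes rose in ischemic myocardium, which may come from a change of cell types as well as from transcription within cells. Fewer cardiomyocyte nuclei that each transcribe as before would lower by 1 factor all genes that cardiomyocytes alone transcribe. The 26 genes of the sarcomere, calcium handling and transcription factor lists differed beyond their errors, from -3.40 for MYOCD to -0.17 for MEF2C (chi-square of heterogeneity p = 1.8e-25). Some of them, such as PROX1, MYOCD, PLN and DES, are also in the endothelial or smooth muscle list. The 14 sarcomere genes, DES among them, differed too, from -2.97 for CSRP3 to -0.45 for ANKRD1 (chi-square of heterogeneity p = 9.5e-11). Genes that other cells transcribe too would fall unequally, so neither chi-square test can decide this. A lower share of cardiomyocytes alone would raise other cell types alike, and the comparison first set for this, macrophage against endothelial genes, missed the threshold (1.44 log2 units apart, permutation p = 0.0803). In a comparison set after that miss, 17 macrophage and neutrophil genes lay 2.07 above the 12 endothelial and smooth muscle genes that no heart muscle list holds (permutation p = 0.00715). They lay 2.25 above all 16 (permutation p = 0.00057) and 2.07 above the 10 endothelial genes (permutation p = 0.0187). The permutations shuffled genes, which are not independent replicates. S100A8, S100A9 and S100A12 held no healthy reads and passed the filter only through the other groups, which fixes the sign of their change. These tests therefore cannot decide whether a lower share of cardiomyocytes is the whole account. Entry of leukocytes and stronger transcription within resident leukocytes both stay open, since these differences restate the pattern and the libraries hold no count of cells, and of the listed genes CD14 (0.714 RPKM in healthy and 14.4 in ischemic myocardium), S100A8 (0 and 8.72) and S100A12 (0 and 8.12) were higher, while the macrophage genes C1QA (0.687 and 0.49) and C1QC (0.586 and 0.383) were not higher.

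More microRNA loci held no read in ischemic myocardium, 30 of 55 there against 12 in healthy myocardium. Depth may account for this outside the muscle list. Reads over all 55 loci, scaled to library size, were 1.12 times the healthy level. Outside the muscle list they were 1.74 times that level, and in the muscle list 0.392 times and lower in 3 of 3 pigs. The last ratio rests largely on MIR208B, which lies inside MYH7, since it was 0.672 without that locus, and it was 0.216 without MIR29B-1, so whether the muscle loci fell as a set stays open.

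Among the 2244 positions of at least 300 bp, shorter ones tended to have higher log2 fold changes in ischemic against healthy myocardium. The Spearman correlation of span and change was -0.167 (bootstrap SD 0.0225), and -0.191, -0.149 and -0.174 in pigs 1 to 3. It was -0.136 in border zone against healthy myocardium. In ischemic against healthy myocardium medians were 0.55 from 300 to 1000 bp and 0.70 from 1000 to 3000 bp. They were 0.04 from 30000 to 100000 bp and -0.07 above that. Lower depth is argued against by the correlation with reads thinned to the shallowest library (-0.205). The span of the genes in the fixed lists is argued against by the correlation without them (-0.144). Mature RNA in the nascent preparation may take part, since at a given span positions with more exon sequence rose more (partial correlation 0.137), and whether it takes part in the rise of ribosomal protein genes stays open. A change of elongation was not tested.

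Splits of the 6 libraries of each comparison into 3 and 3 number 10, of which 4 part every pig, too few for a share under 0.05, since 1 split, the real one, gave as many in each case. The real splits gave 659, 143 and 27 positions in ischemic against healthy, border zone against healthy and ischemic against border zone myocardium, and the highest of the others 2, 1 and 3. Among splits that part every pig the highest others gave 1, 1 and 0 (limma). For lists the real splits gave 18, 14 and 17 and the highest others 11, 12 and 10, or 8, 11 and 4 among splits that part every pig. The other splits leave pigs or groups mixed.

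Among positions with 1 to 30 reads, counts that are multiples of 3 made up 32.8% to 53.2% of values per library, with 322 positions at 3 reads against 55 at 1 read and 52 at 2 reads in ischemic replicate 3.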
